A study of Rattus norvegicus with 8 samples.

How the data were processed

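Expression was measured on 8 two-colour Agilent arrays of 1 slide, with 62976 spots each, 58717 of them non-control spots for 30367 probes. Treated RNA was labelled with Cy5 and vehicle RNA with Cy3 on every array, per the labels, so a ratio above 0 on the log2 scale means more in the treated sample. The labels do not say whether the vehicle RNA was 1 pool. Across genes, the vehicle channels correlated at r between 0.997 and 0.999 and the treated channels between 0.993 and 0.998. With each channel quantile-normalised, the median SD across arrays was 0.0785 for vehicle and 0.129 for treated samples. Vehicle thus varied less than the treated samples, but the channels also differ in dye, so this does not settle the question. The deposited scanner files hold spot intensity (median pixel brightness per channel, before background subtraction) with the local background intensity. They also hold a log10 ratio of red over green that was background-subtracted and dye-normalised by Agilent Feature Extraction 11.5, per the file headers and the submitters' processing notes. The deposited series table holds the same log10 ratios (largest difference 0.00500), with a median of 0 on each array, and served as an alternative. The spot flags for background, outliers and saturation are 0 or 1 per the file headers, and 0 spots were saturated.

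From the intensities, background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and each array was normalised by loess with control spots at weight 0. Median signals were used in place of the mean signals that had been planned, since the tables used here hold medians. Spots with outlier flags (902 to 1262 per array) were left out, and spots of a probe were averaged. A probe was tested where it was well above background in either channel on at least 2 of 8 arrays (25363 probes, of which 67 lacked a value on some array and were left out). A gene was represented by its brightest tested probe, and 2173 genes had several. Probes were named by matching their accession, without version, to the RefSeq table of the GRCr8 assembly: 17998 of 30367 probes had a symbol, and 12944 of the 22459 genes and accessions tested. No coordinates are given, because the arrays were designed on another build. The median signal was 97 to 127.5 in Cy5 on 7 arrays and 87.5 in ADDL+CAT-SKL 2, over backgrounds of 23.5 to 26.

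Groups were compared with limma (lmFit and eBayes) over all samples, which share 1 estimate of the spread, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Vehicle was the only control, so treatments were tested as a ratio against 0. This leaves out the spread of the vehicle cultures and cannot separate a dye effect of a probe from the treatment. Treatments were also compared with one another. The plan was a fit of 8 samples. After its calls had been seen, duplicate spots showed that the CAT-SKL+ADDL arrays differed by about as much as spot noise over the probes. These arrays were averaged into 1 sample (7 samples, 3 residual degrees of freedom and 5.04 from the prior). A pair counted as 1 sample where the r of its differences between first and second spots was below 0.1, a limit set after the values were seen. Results with 8 samples are given as an alternative. Single treatments lasted 24 h and sequential ones 24 h for each agent. The single treatments lay in another row of the slide than the sequential ones, so position and duration cannot be told apart from the sequence of agents. The p-values measure the spread between these samples only.

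The 26 gene lists were fixed before the data were examined and had 533 of 584 members measured. They were tested with camera (preset correlation 0.01, two-sided), again with an estimated correlation, under which no list passed in any comparison, and with fry, which asks whether a list moves on balance without setting it against other genes; fry called the GABAergic list after CAT-SKL (adjusted p = 0.0398) and no other. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed beforehand: against vehicle the 10 largest rises and 10 largest falls that passed with the same sign on both arrays, between treatments the 5 largest of each with arrays that did not overlap, otherwise the 5 with the smallest p, always with a symbol, plus up to 4 members per list with the smallest p, and Cat throughout. Some genes that the rule selects are not listed in the text. Errors are standard errors of limma, which pool the spread over groups.

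The functions were tested on simulated data with 22459 genes, whose variances were drawn from the distribution that limma fitted to the arrays. That draw was chosen after a first version, which used the SD of each gene, had been seen. The first version gave 0 to 51 calls for an unchanged CAT-SKL group against 1 shared vehicle sample and a prior of 2.22 degrees of freedom, whereas the later draw gave 227 to 668 calls and a prior of 5.08, beside 5.04 for the arrays. The later draw used the 5.04 of the arrays as its setting, so its prior had to come out close. For CAT-SKL against vehicle, 85.6% of 200 genes changed by 0.5 on the log2 scale were recovered, and 0% of those changed by 0.25. For CAT-SKL+ADDL against vehicle, 0% were recovered at 0.5 and 96.6% at 1. For ADDL+CAT-SKL against ADDL, 0.4% were recovered at 0.5 and 97.2% at 1. A shift of 0.3 in the astrocyte list after CAT-SKL was called in 10 of 10 simulated sets with the preset correlation and in 6 with an estimated one. Genes were simulated as independent, so this does not test the preset correlation for lists whose members move together. Unchanged groups against 1 shared vehicle sample were simulated in 100 draws with the same variances for treated and vehicle samples, once with each version. Alternatives covered the background correction, normalisation, filter, probe rule, outlier flags, replicate number as a block, single channel, deposited ratios and each array left out, and, chosen after seeing the data, the number of samples and a trend over array columns. Figures were drawn with matplotlib 3.10.9.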

Results

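Gene expression was measured in primary neurons from the cortex and hippocampus of Sprague Dawley rat embryos (E18) that had been kept for 7 days in vitro. ADDL are soluble oligomers made from amyloid-beta, the peptide that accumulates in Alzheimer's disease. CAT-SKL is an antioxidant protein built on catalase, the enzyme that breaks down hydrogen peroxide, and carries a targeting signal for peroxisomes. The study asked which genes change in ADDL-treated neurons with and without CAT-SKL. The 8 two-colour arrays fell into 4 groups of 2: CAT-SKL alone, ADDL alone, CAT-SKL followed by ADDL (CAT-SKL+ADDL) and ADDL followed by CAT-SKL (ADDL+CAT-SKL), each agent at 1 µM for 24 h. The order in a combined name was taken as the order of treatment. Every array set a treated sample in Cy5 against vehicle-treated neurons in Cy3, with no dye swap. Between 73.3% and 81.0% of the probes were well above background in Cy5 and between 71.5% and 77.4% in Cy3, and the small number of arrays limits the precision.

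The labels call the arrays of a group biological replicates. On 13221 probes with 2 spots, the CAT-SKL+ADDL arrays differed from each other by about the noise between spots. The SD of their difference was 0.0778 on the log2 scale, against 0.0764 from spot noise alone. Single genes could differ by far more, such as Xpnpep2 (-0.06 and -1.25). The difference of these arrays on the first spots did not carry over to the second spots (r = 0.00744 across probes, which are not independent replicates). For the 27 other pairs of arrays that r lay between 0.290 and 0.709, and the ratio of SDs between 1.24 and 2.07 in place of 1.02. The CAT-SKL+ADDL arrays were therefore averaged and counted as 1 sample, which leaves 7 samples and assumes that the lone sample varies like the other groups. This counting was chosen after the fit with 8 separate samples had been seen, and the counts of that fit stand beside the others.

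**Figure D1:**
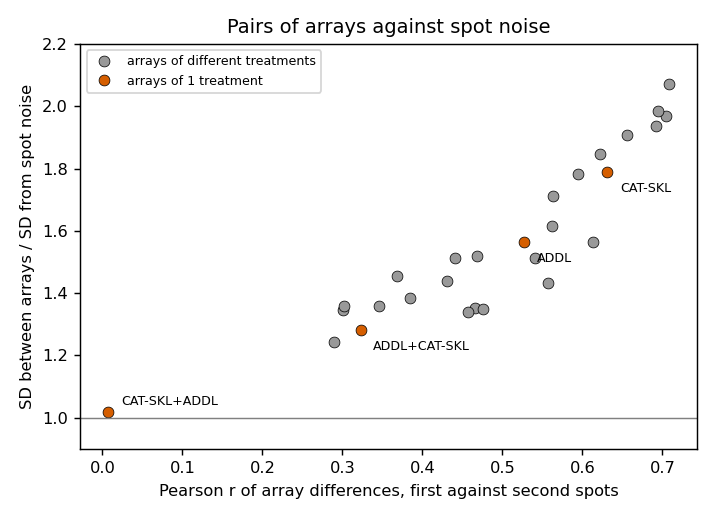
Each point is a pair of arrays; the x axis gives the Pearson r across 13221 probes between the difference of the arrays on the first spots and on the second spots, and the y axis the SD between the arrays over the SD from spot noise (no unit). The CAT-SKL+ADDL pair sits at r = 0.00744 and a ratio of 1.02, while the other 27 pairs begin at r = 0.290 and a ratio of 1.24.

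CAT-SKL alone was set against vehicle to ask what the antioxidant does without added oligomers. After CAT-SKL, 564 of the 22459 genes and unnamed accessions tested passed the threshold, 176 higher and 388 lower, with a median absolute log2 change of 0.40, and 4 of them changed at least 2-fold. Among the largest rises were Pdgfra, a growth factor receptor of oligodendrocyte precursors (log2 change 1.19 ± 0.21, SE, n = 2, adjusted p = 0.0402), and Cort, a neuropeptide related to somatostatin (1.04 ± 0.12, adjusted p = 0.0214). The 10 largest also included Cyba, a subunit of NADPH oxidase (0.95 ± 0.14, adjusted p = 0.0316), and Crh, corticotropin-releasing hormone (0.78 ± 0.07, adjusted p = 0.0214). Pdpn (1.08), Scrg1 (0.94), Gramd2b (0.85), Cfap52 (0.78), the tubulin gene Tuba1a (0.76) and the sphingosine-1-phosphate receptor gene S1pr1 (0.75) also rose; another probe of Pdpn gave 0.33. Of the genes with a symbol, the linker histone gene H1f4 fell most (log2 change -0.70 ± 0.07, SE, n = 2, adjusted p = 0.0214). Foxe1 (-0.66), the vesicle priming gene Unc13a (-0.63), the postsynaptic scaffold gene Lrrc7 (-0.62), Tmem178b (-0.62), the actin regulator Wasl (-0.61), Slk (-0.61), the chromatin remodeller Chd2 (-0.60) and Usp36 (-0.58) fell as well, and another probe of Tmem178b gave -0.02. The catalase gene Cat did not pass (-0.16 ± 0.09, SE, n = 2, adjusted p = 0.390).

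Of the lists fixed before the data were examined, genes of inhibitory (GABAergic) neurons lay above vehicle after CAT-SKL, with a median log2 change of 0.14 over 24 measured members (camera adjusted p = 0.000926; adjusted p = 0.521 with an estimated correlation). In this list 4 genes rose over all genes tested and, adjusted over the list alone, 8 rose and 2 fell. The neuropeptide gene Npy (0.72 ± 0.08), the vesicular GABA transporter gene Slc32a1 (0.73 ± 0.11), the calcium-binding protein gene Calb1 (0.45 ± 0.08) and Gad1, which makes GABA (0.56 ± 0.10), passed over all genes, and other probes of Npy and Gad1 gave 0.68 and 0.11. Oligodendrocyte lineage markers (median 0.06, camera adjusted p = 0.0253) had 3 of 15 members that rose over all genes and 5 adjusted over the list alone. The former were Pdgfra and the transcription factor genes Olig2 (0.50 ± 0.09) and Sox10 (0.57 ± 0.11), while another probe of Olig2 gave 0.01. Astrocyte markers had the highest median of the lists, 0.40, with camera adjusted p = 9.78e-07; 0 of 16 passed over all genes in limma and 11 rose adjusted over the list alone. Their strongest members were S100b (1.06 ± 0.23), the gap junction gene Gja1 (0.96 ± 0.22) and the glutamate transporter gene Slc1a3 (0.85 ± 0.20), and other probes of S100b and Slc1a3 gave 0.19 and 0.50. Proliferation and progenitor genes (median 0.19, camera adjusted p = 9.78e-07) included 1 of 19 that rose over all genes, the mitotic gene Birc5 (0.37 ± 0.07), and 9 that rose adjusted over the list alone. With an estimated correlation the adjusted p was 0.521 for each of these lists. The medians in CAT-SKL 1 and 2 were 0.69 and 0.17 for astrocyte markers, 0.17 and 0.080 for GABAergic genes, 0.17 and 0.031 for oligodendrocyte lineage markers and 0.29 and 0.12 for proliferation and progenitor genes. GABAergic genes also had medians of 0.14 and 0.090 in ADDL 1 and 2, although camera did not call the list there. Without CAT-SKL 1 the oligodendrocyte list was no longer called (camera adjusted p = 0.408).

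Antioxidant targets of NRF2 were higher as a list after CAT-SKL (median 0.12 over 20 members, camera adjusted p = 0.00223, adjusted p = 0.521 with an estimated correlation), with 0 passing over all genes in limma and 7 that rose adjusted over the list alone. Hmox1, which degrades haem, had a log2 change of 0.48 ± 0.11, the ferritin genes Fth1 and Ftl1 had 0.21 ± 0.05 and 0.24 ± 0.06, and Gclc, of glutathione synthesis, had 0.25 ± 0.07. The medians of the NRF2 targets were 0.17 and 0.10 in CAT-SKL 1 and 2, beside 0.69 and 0.17 for astrocyte markers, and -0.011 beside -0.022 in ADDL+CAT-SKL 2. In ADDL 1 and 2 they were 0.061 and 0.10, beside 0.30 and 0.58. In CAT-SKL+ADDL 1 and 2 they were 0.10 and 0.15, beside 0.47 in each, and in ADDL+CAT-SKL 1 they were 0.11 beside 0.19. Camera did not call the NRF2 list after ADDL or ADDL+CAT-SKL. Inflammation genes (median 0.07 over 22 members, camera adjusted p = 0.0105) held 1 that rose over all genes, the chemokine gene Ccl3 (0.49 ± 0.10), and 3 adjusted over the list alone. Cholesterol synthesis genes lay below vehicle (median -0.11 over 22 members, camera adjusted p = 0.00289); Cyp51 (-0.38 ± 0.07) was among those that fell over all genes, and 6 fell adjusted over the list alone. Immediate early genes, which respond to activity, had a median of -0.12 over 24 members (camera adjusted p = 0.0226, and 1 rose and 2 fell adjusted over the list alone). This median was -0.32 in CAT-SKL 1 and 0.086 in CAT-SKL 2, and without CAT-SKL 1 the list was called in the opposite direction (camera adjusted p = 0.0496). The cholesterol synthesis median was -0.15 and -0.076 in these arrays. With an estimated correlation the adjusted p was 0.677 for the immediate early genes and 0.521 for the inflammation and cholesterol lists. Of 24 presynaptic genes, a list that was not called (camera adjusted p = 0.0747), 1 rose and 3 fell over all genes and 2 rose and 5 fell adjusted over the list alone, with Unc13a and Cplx2 (-0.41 ± 0.07) among the former falls.

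The CAT-SKL count was 1814 (774 higher, 1040 lower) with 8 separate samples, 1819 (1417 higher, 402 lower) with arrays centred on their median in place of loess, and 0 with the deposited log ratios. It was 2 without CAT-SKL 1, 63 without either ADDL array and 214 without either ADDL+CAT-SKL array. Camera called 13 lists without CAT-SKL 2. With the replicate number as a block, 37 of 40 named genes of CAT-SKL and ADDL+CAT-SKL lost the threshold. The ratio was tested against 0, which leaves out the spread of the vehicle cultures. Simulated unchanged groups, fitted as 7 samples and set against 1 vehicle sample with the spread of a treated sample, gave a median of 448.5 genes (227 to 668 in 100 draws) with variances from the distribution fitted to the arrays, and 0 (0 to 51) with the SD of each gene. Whether the 564 genes exceed what such a vehicle could give therefore depends on these variances. The number of genes with an unadjusted p below 0.05 did not exceed either simulation. It was 4755 for CAT-SKL, against 4798 to 5101 with fitted variances and 4520 to 4807 with the SD of each gene. The fitted variances gave a prior of 5.08 degrees of freedom, close to the 5.04 of the arrays, and the SD of each gene gave 2.22. The fitted variances were drawn with the prior of the arrays, so their likeness was fixed in advance and is no support for that version. With the fitted variances the 564 genes lay within the range of unchanged groups.

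ADDL alone was set against vehicle to ask what the oligomers change. No gene passed the threshold in limma, where 4268 genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.0709. By chance 1123 would be expected if vehicle had no spread. Simulated unchanged groups, made for CAT-SKL with n = 2 as here, gave 4798 to 5101 against 1 shared vehicle sample with fitted variances. With the SD of each gene they gave 4520 to 4807, so the observed number lay below both ranges. The named genes with the smallest p were Mphosph6 (log2 change 0.51 ± 0.05, SE, n = 2; another probe gave -0.10), the tubulin genes Tuba1a (0.76 ± 0.10) and Tubb4b (0.48 ± 0.06), Spag7 (0.70 ± 0.09) and Birc5 (0.52 ± 0.07). Cat had a log2 change of -0.26 ± 0.09 (adjusted p = 0.197), with -0.48 in ADDL 1 and -0.03 in ADDL 2.

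As lists, immediate early genes lay below vehicle after ADDL (median -0.24 over 24 members, camera adjusted p = 4.28e-06; adjusted p = 0.662 with an estimated correlation). In limma 0 of them passed over all genes and 13 fell adjusted over the list alone, among them Inhba, a subunit of activin (-0.91 ± 0.21), Gadd45b (-0.35 ± 0.09), the synaptic scaffold gene Homer1 (-0.28 ± 0.07) and the phosphatase gene Dusp1 (-0.38 ± 0.10). Astrocyte markers had a median of 0.44 (camera adjusted p = 9.09e-09), and 14 of 16 rose adjusted over the list alone, with Slc1a3 at 1.01 ± 0.20 and Slc1a2, another glutamate transporter gene, at 0.39 ± 0.06. Proliferation and progenitor genes had a median of 0.21 (camera adjusted p = 3.40e-07; 10 of 19 rose adjusted over the list alone, with the nucleotide reductase gene Rrm2 at 0.86 ± 0.15 and the replication gene Mcm3 at 0.49 ± 0.08). Microglia markers (median 0.13, camera adjusted p = 0.000338, 6 of 17 rose adjusted over the list alone), interferon response genes (0.09, 0.00497, 4 of 19) and oligodendrocyte lineage markers (0.06, 0.00713, 5 of 15) followed. Among them were Fcer1g at 0.39 ± 0.07 and Olig2 at 0.63 ± 0.09. Other probes of Rrm2, Mcm3, Olig2, Slc1a3 and Slc1a2 gave 0.12, 0.30, -0.01, 0.80 and 0.56. The unfolded protein and integrated stress response had a median of 0.11 over 24 members (camera adjusted p = 0.0292), of which 5 rose and 1 fell adjusted over the list alone. The transcription factor gene Atf3 was at 0.40 ± 0.08 and Herpud1 at 0.45 ± 0.10. The median of this list was 0.18 in ADDL 1 and 0.026 in ADDL 2, and it was not called without ADDL 1 (camera adjusted p = 0.363) or without either ADDL+CAT-SKL array (0.0575). Microglia markers, at 0.19 and 0.083, were not called without ADDL 1 (0.107), and oligodendrocyte lineage markers had medians of 0.14 and 0.096. Each of these lists had an adjusted p of 0.662 with an estimated correlation, and 0 of their members passed over all genes in limma. The count of changed genes was 974 with 8 separate samples, 430 with median centring, 374 without either CAT-SKL array and 3 without ADDL 2, and simulated unchanged groups against 1 shared vehicle sample gave a median of 446.5 (222 to 651) with fitted variances and 0 (0 to 47) with the SD of each gene, so the former gave more calls than the arrays did.

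CAT-SKL followed by ADDL was set against vehicle as the pre-treatment arm. No gene passed in limma over the lone sample, with 2543 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.17. Cort (log2 change 1.25 ± 0.17, SE from the pooled spread, n = 1), the myosin gene Myh8 (0.60 ± 0.09) and the exonuclease gene Isg20 (-0.58 ± 0.08) were among the genes with the smallest p. Xpnpep2 (-0.66) and Inhbb (-0.50) were also among them, but their arrays gave -0.06 and -1.25, and -0.05 and -0.95, and another probe of Inhbb gave 0.15. Cat was at -0.10 ± 0.13. Camera called 12 lists, 7 higher and 5 lower, in a comparison that rests on 1 sample with a spread taken from the other treatments. The higher ones were proliferation and progenitors (median 0.26, adjusted p = 1.61e-10), astrocyte (0.49, 2.42e-09) and oligodendrocyte lineage markers (0.35, 0.00127), NRF2 targets (0.14, 0.000542), GABAergic genes (0.11, 0.00228), heat shock chaperones (0.10, 0.00849) and genes of peroxide and superoxide removal (0.10, 0.0253). The lower ones were cholesterol synthesis (-0.16, 0.000542), immediate early (-0.13, 0.0133), presynaptic (-0.11, 0.0149), neuronal identity (-0.09, 0.0253) and p53 target and apoptosis genes (-0.11, 0.0427). The adjusted p with an estimated correlation lay between 0.348 and 0.688 for all 12. Without CAT-SKL+ADDL 1 the neuronal identity list was not called (camera adjusted p = 0.0533) and the presynaptic median was -0.070. Without CAT-SKL+ADDL 2 the peroxide and p53 lists were not called. These arrays differ by about as much as spot noise over the probes, so leaving 1 out does not measure the spread between dishes.

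Within these lists 0 members passed over all genes in limma, while adjusted over the list alone 7 of 16 astrocyte, 7 of 15 oligodendrocyte lineage and 9 of 19 proliferation genes rose. Gja1 was at 1.36 ± 0.32, Pdgfra at 1.21 ± 0.30 and Rrm2 at 1.08 ± 0.21 (another probe gave 0.34). Adjusted in the same way, 6 GABAergic genes rose and 2 fell, 1 presynaptic gene rose and 4 fell, and 2 cholesterol synthesis genes fell, with Slc32a1 at 0.74 ± 0.16 and Mvd at -0.32 ± 0.07. With 8 separate samples 2312 genes passed for CAT-SKL+ADDL against vehicle, 325 with median centring, 5 without CAT-SKL+ADDL 1 and 4 without either CAT-SKL array. The test assumes that the lone sample varies like the other groups.

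ADDL followed by CAT-SKL was set against vehicle as the post-treatment arm. In this group 100 genes passed, 53 higher and 47 lower, 8 of them by at least 1.5-fold, with a median absolute log2 change of 0.43. Of the genes with a symbol, the chemokine gene Ccl3 rose most (0.76 ± 0.10, SE, n = 2, adjusted p = 0.0448), followed by the thioredoxin-related gene Tmx4 (0.61 ± 0.07), Nceh1 (0.59 ± 0.09), and Crh (0.56 ± 0.07). The nuclear import gene Kpna2 (0.54 ± 0.08), Prps1 (0.50 ± 0.07), Mphosph6 (0.49 ± 0.05), Plppr4 (0.49 ± 0.07), the muscarinic receptor gene Chrm3 (0.48 ± 0.06) and Ssr1 (0.48 ± 0.07) rose too. Other probes of Tmx4, Nceh1, Prps1, Mphosph6, Plppr4 and Ssr1 gave 0.15, 0.05, 0.17, -0.13, -0.14 and -0.03, whereas another probe of Crh gave 0.61. Ypel3 (-0.51 ± 0.07), the endocytosis gene Epn1 (-0.49 ± 0.06), Albfm1 (-0.48 ± 0.07), the ribosomal RNA transcription factor gene Ubtf (-0.48 ± 0.07) and the synaptic vesicle gene Vamp2 (-0.47 ± 0.06) fell, each with adjusted p = 0.0448. Rbp4 (-0.47 ± 0.06), Emc9 (-0.46 ± 0.06), Efemp2 (-0.46 ± 0.06), Ptges3l1 (-0.45 ± 0.07) and Ak5 (-0.45 ± 0.06) fell with the same adjusted p, and another probe of Ubtf gave -0.12. Cat was at -0.26 ± 0.09 (adjusted p = 0.203).

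Proliferation and progenitor genes were higher as a list after ADDL+CAT-SKL (median 0.11, camera adjusted p = 0.00473; 5 of 19 rose adjusted over the list alone), as were inflammation genes (0.04, 0.0192; 3 of 22), immediate early genes (0.10, 0.0364; 3 rose and 1 fell of 24) and GABAergic genes (0.06, 0.0364; 3 of 24). With an estimated correlation the adjusted p was 0.660 for the inflammation and GABAergic lists and 0.975 for the other 2. Ccl3 was the inflammation gene that rose over all genes, and in the other 3 lists 0 members passed in limma. The heat shock gene Hspa8 (0.44 ± 0.05), the antigen presentation gene B2m (0.43 ± 0.07), the glutamate transporter gene Slc17a6 (0.41 ± 0.06) and the ribosomal protein gene Rpl23 (0.37 ± 0.05) rose and the adhesion gene Ncam1 (-0.40 ± 0.06) fell outside these lists. The 3 other probes of Hspa8 gave 0.05, 0.02 and -0.15. The ADDL+CAT-SKL count was 893 with 8 separate samples, 374 (297 higher, 77 lower) with median centring. It was 0 with the deposited log ratios or with the replicate number as a block. It was also 0 without background subtraction, without a filter on dim probes or after removal of a trend over the array columns. Leaving out either CAT-SKL array, either ADDL array or ADDL+CAT-SKL 1 gave 0, and leaving out ADDL+CAT-SKL 2 gave 1. Camera called 0 lists without ADDL+CAT-SKL 1 and 6 without ADDL+CAT-SKL 2. The medians in ADDL+CAT-SKL 1 and 2 were 0.26 and 0.011 for proliferation and progenitors, 0.14 and 0.014 for GABAergic, 0.038 and 0.15 for immediate early and 0.066 and 0.065 for inflammation genes. The immediate early list was also not called without ADDL+CAT-SKL 2 (camera adjusted p = 0.113) or either ADDL array (0.0684). Simulated unchanged groups against 1 shared vehicle sample gave a median of 439.5 genes (269 to 600) with fitted variances and 0 (0 to 52) with the SD of each gene, and the observed 100 lay between these ranges.

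**Figure D2:**
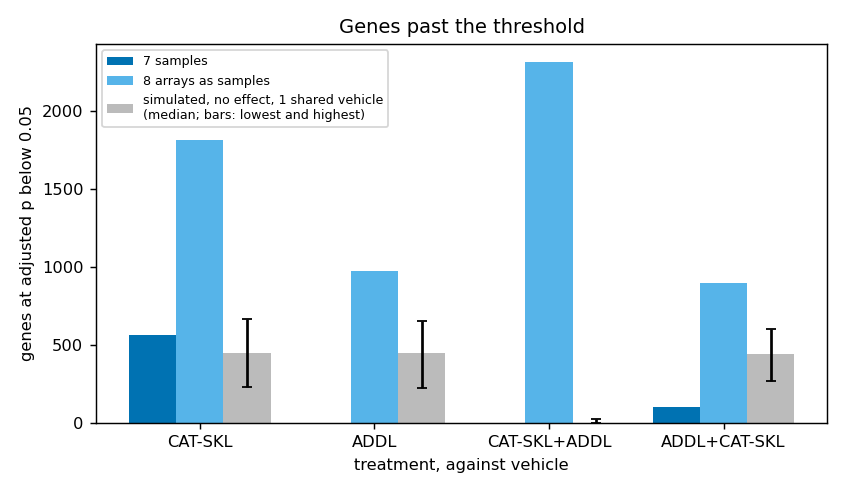
Number of genes past the threshold against vehicle (y axis, genes) for each treatment (x axis), with 7 samples, with 8 arrays as separate samples, and as the median of 100 simulated sets without any effect against 1 shared vehicle sample, where bars span the lowest and highest set. The simulated variances come from the distribution fitted to the arrays. With the SD of each gene, which is not drawn, the simulated median for CAT-SKL was 0 (0 to 51). The simulation was made for the fit of 7 samples alone, so the counts of that fit are the ones to set beside it: 564 genes for CAT-SKL beside a median of 448.5, and 0 for CAT-SKL+ADDL beside 1.5. The counts with 8 samples (1814 and 2312) have no simulated counterpart.

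The treatments were compared with one another to ask whether CAT-SKL alters the response to ADDL, a contrast in which dye effects and a shared vehicle cancel. Differences between separate vehicle samples would not cancel, and the labels do not say whether the vehicle RNA was 1 pool. Immediate early genes were higher in ADDL+CAT-SKL than in ADDL (median log2 difference 0.33 over 24 members, camera adjusted p = 2.26e-11; adjusted p = 0.877 with an estimated correlation). In limma 0 of them passed over all genes and 10 were higher adjusted over the list alone, including Klf4 (0.46 ± 0.10, SE, n = 2 in each group), the transcription factor gene Egr2 (0.70 ± 0.17) and the activity-regulated synaptic gene Arc (0.67 ± 0.17). Astrocyte markers (-0.40, camera adjusted p = 1.58e-05), oligodendrocyte lineage markers (-0.19, 0.00598), microglia markers (-0.15, 0.000234) and the unfolded protein and integrated stress response (-0.11, 0.0138) were lower in ADDL+CAT-SKL than in ADDL. S100b was at -0.80 ± 0.32, Olig2 at -0.63 ± 0.12, Laptm5 at -0.43 ± 0.10 and the stress gene Ddit3 at -0.28 ± 0.11. Other probes of S100b and Olig2 gave -0.07 and 0.03. For these 4 lists the adjusted p with an estimated correlation was 0.877, 0 members passed over all genes in limma, and 0, 2, 1 and 0 were lower adjusted over the list alone. No single gene passed in limma (1897 at an unadjusted p below 0.05, smallest adjusted p 0.570). The smallest p belonged to Man1a1 (0.57 ± 0.09), the somatostatin receptor gene Sstr3 (0.44 ± 0.07), Srxn1, which repairs peroxiredoxins (0.52 ± 0.09), the cadherin gene Cdh6 (-0.73 ± 0.13) and Crem (0.70 ± 0.12), and Cat differed by -0.01 ± 0.13. The count was 30 (26 higher, 4 lower) with median centring, 13 without either CAT-SKL array and 2 without ADDL 2. Of the 5 lists, immediate early genes were called with each array left out. Without ADDL 1 the stress response (median -0.068, camera adjusted p = 0.289) and microglia markers (-0.064, 0.0515) were not called, nor without ADDL+CAT-SKL 1 (0.162 and 0.0526). Without ADDL 2 astrocyte (-0.25, 0.0545) and oligodendrocyte lineage markers (-0.14, 0.0985) were not called.

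CAT-SKL+ADDL was compared with ADDL as a lone sample, without a spread of its own. Camera called 3 lists: peroxide and superoxide removal (median difference 0.08) and oxidative phosphorylation (0.09) were higher and microglia markers (-0.13) lower in CAT-SKL+ADDL, each with camera adjusted p = 0.0280 and adjusted p = 0.766 with an estimated correlation. Prdx1, a peroxiredoxin gene, differed by 0.43 ± 0.14, the cytochrome c oxidase subunit gene Ndufa4 by 0.25 ± 0.10 and the microglial gene P2ry12 by -0.19 ± 0.09, and 0 members of these lists passed over all genes or adjusted over the list alone. No gene passed in limma (876 at an unadjusted p below 0.05 against 1123 by chance, smallest adjusted p 0.999). Xpnpep2 (-0.61) and Sfxn1 (-0.71) were among the genes with the smallest p, but the CAT-SKL+ADDL arrays gave -0.06 and -1.25 for Xpnpep2 and 0.06 and -1.63 for Sfxn1. The cytokine receptor subunit gene Il6st (-0.57 ± 0.10), Trappc2 (0.53 ± 0.10) and Slc25a28 (-0.41 ± 0.09) followed, and Cat differed by 0.15 ± 0.16. Without CAT-SKL+ADDL 1 the count of genes was 3, without CAT-SKL+ADDL 2 the count of lists was 0, without ADDL 2 it was 5, and without either CAT-SKL array it was 6. Without ADDL 1 none of the 3 lists was called (camera adjusted p = 0.216 for peroxide removal, 0.149 for oxidative phosphorylation and 0.546 for microglia markers). The median for microglia markers was then -0.035, against -0.20 without ADDL 2 or CAT-SKL+ADDL 1 and -0.084 without CAT-SKL+ADDL 2. The median for peroxide removal was 0.041 without ADDL 1.

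The order of treatment was compared directly, with 1 sample for CAT-SKL+ADDL, whose spread between dishes was not measured. For astrocyte markers the replicates of CAT-SKL had a median difference of 0.57, more than the difference given here. In CAT-SKL+ADDL relative to ADDL+CAT-SKL, astrocyte markers (median difference 0.46, camera adjusted p = 9.51e-06), oligodendrocyte lineage markers (0.42, 0.000420), proliferation and progenitor genes (0.18, 0.000159), peroxide and superoxide removal (0.07, 0.00689) and oxidative phosphorylation (0.07, 0.0435) were higher. Immediate early genes (-0.22, 8.14e-06) and cholesterol synthesis genes (-0.10, 0.000420) were lower. Gja1 differed by 1.15 ± 0.39 (SE, n = 1 against 2), the myelin gene Mbp by 1.98 ± 0.51, Mcm3 by 0.54 ± 0.14, the peroxiredoxin gene Prdx4 by 0.33 ± 0.10, Egr1 by -0.38 ± 0.12 and Sqle by -0.35 ± 0.11. Other probes of Mbp and Mcm3 gave -0.07 and -0.05. With an estimated correlation the adjusted p was 0.622 for the astrocyte, oligodendrocyte, peroxide, cholesterol and oxidative phosphorylation lists and 0.686 for the other 2. Adjusted over the list alone, 5 of 15 oligodendrocyte lineage genes were higher and 0 members of the other lists passed. No gene passed in limma (1268 at an unadjusted p below 0.05, smallest adjusted p 0.848). Septin7 (0.81 ± 0.15), Pogz (0.50 ± 0.09), Rsl24d1 (0.63 ± 0.12) and Trappc2 (0.54 ± 0.10) had the smallest p with Xpnpep2 (-0.67), and another probe of Pogz gave 0. Cat differed by 0.16 ± 0.16. The count was 5 with median centring, 4 without either CAT-SKL array and 3 without CAT-SKL+ADDL 1. The oxidative phosphorylation list was called without ADDL+CAT-SKL 1 and with no other array left out (camera adjusted p between 0.0578 and 0.186). Without ADDL+CAT-SKL 2 proliferation (median 0.11, 0.131) and peroxide removal (0.082, 0.0752) were not called and the oligodendrocyte median was 0.20. Cholesterol synthesis was at -0.050 (0.233) without ADDL+CAT-SKL 1 and -0.19 without ADDL+CAT-SKL 2, and peroxide removal at 0.11 without CAT-SKL+ADDL 1 or ADDL+CAT-SKL 1.

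CAT-SKL and ADDL alone differed in no gene that passed in limma (1953 at an unadjusted p below 0.05, smallest adjusted p 0.540) and in 0 of 26 lists. Calb1 was the gene with the smallest p (0.66 ± 0.12, SE, n = 2 in each group), followed by the transcription factor gene Tcf4 (-0.49 ± 0.09), Tmem52b (-0.43 ± 0.08; another probe gave 0.10), Il6st (-0.43 ± 0.08) and Oxr1, an oxidation resistance gene (0.39 ± 0.08), and Cat differed by 0.10 ± 0.13. The count of genes was 8 without CAT-SKL 1, 2 without ADDL 2 and 1 with median centring. Camera called 6 lists without CAT-SKL 1 (1 higher and 5 lower in CAT-SKL), 7 without CAT-SKL 2 (6 higher and 1 lower), 4 without ADDL 1 (2 and 2) and 3 without ADDL 2 (1 and 2), so the balance of directions turned with the CAT-SKL array kept.

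**Figure D3:**
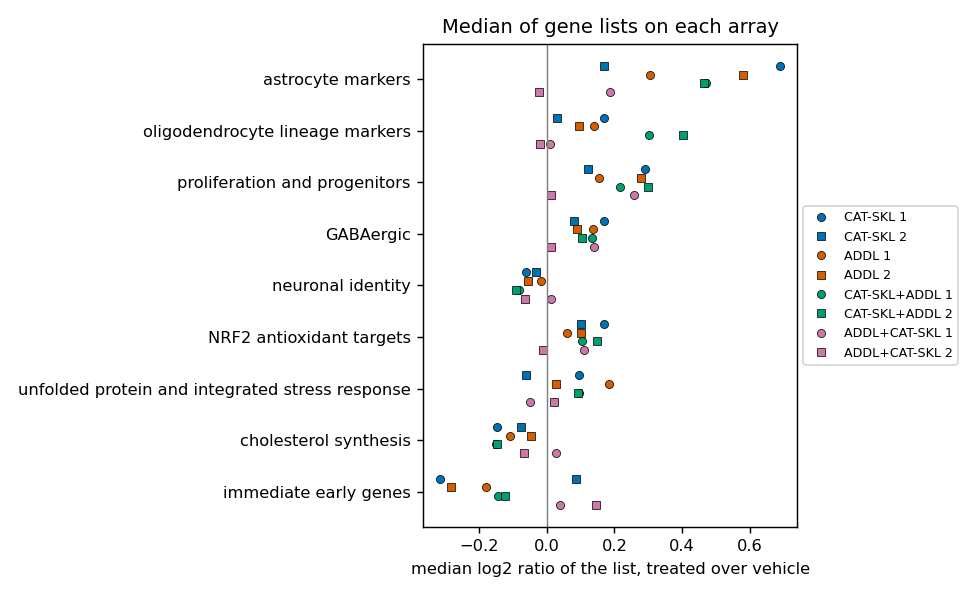
Median log2 ratio of treated over vehicle (x axis) of 9 gene lists (y axis) on each of the 8 arrays; colours mark the treatment, circles replicate 1 and squares replicate 2. Astrocyte markers range from -0.02 in ADDL+CAT-SKL 2 to 0.69 in CAT-SKL 1, and immediate early genes from -0.32 in CAT-SKL 1 to 0.15 in ADDL+CAT-SKL 2.

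Genes with a large ratio on 1 ADDL array were read on the others, although no gene passed for ADDL. The 28 genes with an absolute log2 ratio of at least 1 in ADDL 2, 27 of them higher, had a median signed log2 ratio of 0.62 in ADDL 1, with 27 genes of the same sign. Their median was 1.31 in CAT-SKL 1 and 0.33 in CAT-SKL 2, 1.13 in each CAT-SKL+ADDL array, and 0.43 and -0.02 in ADDL+CAT-SKL 1 and 2. Chosen on ADDL 1, 6 genes had a median of 0.15 in ADDL 2 and between 0.02 and 0.20 in the other arrays. Glial genes were among the 28 in ADDL 2, such as Slc1a3 (1.30), Gja1 (1.19) and Pdgfra (1.25), which are named here after their values were seen. No test was made on these values, and they do not separate a response to ADDL from a vehicle sample shared by the arrays.

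The 4 profiles against vehicle resembled one another. Changes correlated across genes at r between 0.385 and 0.846, 16.8% of genes had 1 sign in all 7 samples (1830 positive and 1945 negative), and CAT-SKL and ADDL+CAT-SKL shared 22 higher and 14 lower genes, with 0 in opposite directions. Independent lists would share 0.415 and 0.812 genes, and independent samples would give 1.56% of genes with 1 sign. Simulated unchanged groups against 1 shared vehicle sample with the spread of a treated sample gave 25.0% (24.3% to 25.6%), 74 and 71 shared genes, and a mean covariance of 0.0133 (0.0127 to 0.0141) beside the observed 0.0115. With the SD of each gene the simulated covariance was 0.0131 (0.0122 to 0.0145) and the shared genes at most 5 and 6. The covariance and the percentage of genes with 1 sign thus lay below every simulated set under both sets of variances. Such a vehicle therefore gives more likeness between treatments than was seen, while the number of shared genes depends on the variances. The comparison could not count against a shared vehicle, since a covariance above the simulated sets would have left it open. Replicates were not measurably closer to each other than to other treatments, with a mean r of 0.491 within and 0.411 between groups (exact permutation p = 0.219, one-sided, 23 of 105 groupings of the 7 samples; the smallest possible is 0.00952).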

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

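The tests of dye bias and of a trend over the array were written before their results were seen. The tests of astrocyte content, astrocyte share, neuron share and spread between dishes were chosen after, as were the variances in the test of a shared vehicle sample and the counting of 7 samples. In 15 cases a list differed between treatments by camera with a preset correlation, and in none of the 15 with an estimated one. Leaving out 1 array ended the call in at least 1 case for 11 of the 15. The comparisons with CAT-SKL+ADDL, which give 10 of the 15, rest on 1 sample of that treatment, whose spread between dishes was not measured. With that limit, CAT-SKL+ADDL exceeded ADDL in peroxide and superoxide removal (median log2 difference 0.080) and oxidative phosphorylation (0.090) and lay below it in microglia markers (-0.13). ADDL+CAT-SKL exceeded ADDL in immediate early genes (0.33) and lay below it in astrocyte (-0.40), oligodendrocyte lineage (-0.19) and microglia markers (-0.15) and in the unfolded protein and integrated stress response (-0.11), with 2 samples in each group. With 1 sample against 2, CAT-SKL+ADDL exceeded ADDL+CAT-SKL in astrocyte (0.46) and oligodendrocyte lineage markers (0.42), proliferation and progenitors (0.18), peroxide and superoxide removal (0.071) and oxidative phosphorylation (0.073), and lay below it in immediate early (-0.22) and cholesterol synthesis genes (-0.10).

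The log2 ratios had 1 sign in all 7 samples for 16.8% of genes. A single vehicle sample shared by all arrays may account for this, though the labels do not say whether the vehicle RNA was 1 pool. Simulated unchanged groups against such a vehicle gave 24.3% to 25.6% with fitted variances, more than was seen. The mean covariance between treatments was 0.0115, below the simulated sets (0.0127 to 0.0141 with fitted variances, 0.0122 to 0.0145 with the SD of each gene). The simulated vehicle thus overshot the pattern, and a covariance above it would have left this explanation open. Dye bias of single probes cannot be told apart from an effect, since no dye swap was made and 60.4% of 538 other probes of these genes had the same mean sign (95% interval 56.1% to 64.6%), beside 57.1% of 1819 other probes of the remaining genes. A response common to the treatments remains open as well, and the simulation treats genes as independent.

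Astrocyte markers lay above vehicle in 7 of 8 arrays, of which the CAT-SKL+ADDL arrays count as 1 sample. A vehicle sample shared by the arrays would enter all these ratios alike. Astrocyte content that differs from dish to dish may contribute: the median of each sample over the list differed by 0.52 between replicates of 1 treatment, and its treatment means by at most 0.41 (ratio 1.27; exact permutation p = 0.514, 54 of 105 groupings as tight), while the median over genes of their differences was 0.57 between replicates and at most 0.46 between treatments (ratio 1.25). A larger share of astrocytes in the treated dishes cannot be told apart from this: 100% of the bright markers had a mean above 0, which restates the pattern, and their means ran from 0.15 (Slc1a2 and Vim) to 0.79 (Gja1), where a share alone would raise them alike unless other cells express them too. An effect of the treatments on astrocytes or on these genes stays open.

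Immediate early genes were lower in ADDL than in ADDL+CAT-SKL, and with the trend over the array columns removed the median difference was 0.32, which argues against that trend as the whole cause. Fewer neurons in the ADDL dishes would lower neuronal identity genes by as much, but these differed by -0.050. The 95% interval, -0.10 to 0.02, comes from resampling genes of the list and leaves out the spread between dishes. The neuronal medians were -0.019 and -0.056 in ADDL and 0.012 and -0.065 in ADDL+CAT-SKL. These values argue against fewer neurons as the whole cause and leave the direction of the neuronal difference open. Spread between dishes of 1 treatment may contribute. The medians of the immediate early genes in CAT-SKL 1 and 2 differed by 0.40, which is 1.24 times the difference between the treatments (exact permutation p = 0.448, 47 of 105 groupings as tight). The median over genes of the differences between these arrays was 0.36, beside 0.33 between the treatments. The groups compared were tighter than that and did not overlap, with immediate early medians of -0.18 and -0.28 in ADDL and 0.038 and 0.15 in ADDL+CAT-SKL. This list was singled out because it differed between these groups, so the lack of overlap is no separate support. An effect of CAT-SKL after ADDL stays open, as does the longer duration of the sequential treatment.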

How the results depend on the processing

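Counting the CAT-SKL+ADDL arrays as separate samples and removing a trend over array columns were chosen after the data were seen. Against vehicle, the counts of changed genes for CAT-SKL, ADDL, CAT-SKL+ADDL and ADDL+CAT-SKL (564, 0, 0 and 100) became 1814, 974, 2312 and 893 with separate samples and 1819, 430, 325 and 374 with median centring in place of loess, where 395 of the CAT-SKL and 83 of the ADDL+CAT-SKL genes were shared. CAT-SKL gave 850 genes with a stricter filter (18116 genes tested), 280 with no filter, 913 with the trend removed, 14 with the replicate number as a block, and 0 with the deposited log ratios of the arrays or the series table. ADDL+CAT-SKL gave 0 with no background subtraction, no filter, the block, the trend removed or the deposited log ratios of the arrays or the series table. The replicate numbers did not pair the samples (r of replicate differences -0.0901, 0.0780 and -0.202 across genes). With outlier spots kept, CAT-SKL+ADDL gave 4 genes against vehicle, 1 against ADDL and 2 against ADDL+CAT-SKL. Median centring gave 30 genes for ADDL+CAT-SKL against ADDL, 5 between the orders and 1 for CAT-SKL against ADDL; the Cy5 channel alone gave 0 in limma in the 4 comparisons between treatments. With an estimated correlation camera called 0 lists in all 8 comparisons, and with the deposited log ratios 2 for ADDL+CAT-SKL against vehicle and 1 for CAT-SKL+ADDL against ADDL. Leaving out each array gave 2 to 564 genes and 8 to 13 lists for CAT-SKL, 0 to 374 and 6 to 8 for ADDL, 0 to 5 and 10 to 14 for CAT-SKL+ADDL, 0 to 100 and 0 to 6 for ADDL+CAT-SKL, 0 to 3 and 0 to 6 for CAT-SKL+ADDL against ADDL, 0 to 13 and 4 to 6 for ADDL+CAT-SKL against ADDL, 0 to 4 and 6 to 7 between the orders, and 0 to 8 and 0 to 7 for CAT-SKL against ADDL. The immediate early genes after CAT-SKL reversed, from -0.12 to 0.086 without CAT-SKL 1 (camera adjusted p = 0.0496, against 2.40e-10 to 0.677 under the other alternatives), and were at -0.32 without CAT-SKL 2. Genes chosen on ADDL had a median in CAT-SKL+ADDL of 0.21 (chosen on ADDL 1) and 0.63 (ADDL 2) at a lower threshold, and 0.19 and 0.38 with the deposited log ratios. Of 760 values of 40 named genes under the alternatives, 373 kept direction and threshold, 387 kept direction and lost the threshold, and 0 reversed. These genes were chosen with 1 sign on both arrays, so leaving out an array, the block and the number of samples could not reverse them. The averaged CAT-SKL+ADDL sample adds nothing to the spread, so leaving out either of its arrays could not alter the 40 genes. Those kept values are no support. Of 598 values for 46 list results, 502 kept direction and threshold, 95 lost the threshold and 1 reversed. List results in comparisons without CAT-SKL+ADDL likewise could not change when an array of that treatment was left out. Apart from the number of samples or genes tested, the cause was not tested. Signal over background was lowest in ADDL+CAT-SKL 2 (87.5 over 23.5 in Cy5), whose spot SD was 0.126.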

Other observations

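The lists in this part were fixed before the data were examined, and the counting of 7 samples behind the values was chosen after the fit of 8 had been seen. Of the lists not described above, peroxisome genes had medians of 0.00, 0.01, 0.03 and -0.01 after CAT-SKL, ADDL, CAT-SKL+ADDL and ADDL+CAT-SKL, with 1 gene that rose after CAT-SKL, Pex13, which imports peroxisomal proteins (log2 change 0.31). Amyloid and Alzheimer-related genes had medians of -0.08, -0.03, -0.05 and -0.02, and Clu rose after CAT-SKL (0.30). Postsynaptic genes had medians of -0.04, -0.04, -0.05 and -0.02, autophagy and lysosome genes 0.04, 0.00, 0.00 and 0.04, glycolysis and hypoxia genes 0.07, 0.02, -0.01 and 0.03, metallothionein genes -0.03, -0.01, -0.01 and -0.07, and cytosolic ribosomal protein genes 0.01, 0.04, 0.03 and -0.03. Vascular and fibroblast markers (0.04, 0.00, 0.00 and -0.02) and blood cell markers (-0.01, 0.01, -0.03 and -0.01) stayed near 0. Camera called none of these 9 lists in any of the 8 comparisons.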
